A study of Homo sapiens
Mus musculus and Homo sapiens
Mus musculus
Rattus norvegicus with 2 samples.

How the data were processed

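Single-nucleus RNA sequencing was done on grafts of pancreatic progenitors derived from H1, a human embryonic stem cell line. Per the labels, stage 4 progenitors were placed in collagen hydrogels either alone (PP) or with microvessel fragments from rat adipose tissue (PPMV), and the gels were put under the skin of diabetic immunodeficient mice. The series design gives retrieval at 14 weeks and the extract protocol gives 100 days. Grafts from 3 mice were merged into 1 library per group, so the series has 1 PP library and 1 PPMV library. Each group therefore had 1 library, and library and group could not be separated.

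Per the submitters' processing notes, Cell Ranger 3.1 was used with the mm10 and GRCh38 builds. The labels' extract protocol adds a rat assembly to a combined reference and describes gene models that count reads from introns. The feature names in the file carry a GRCh38 pre-mRNA prefix that states the removal of the INS-IGF2 read-through gene. The deposited values were the natural log of 1 plus 10000 times the UMI share of each gene in a nucleus, as tested on the values themselves: after inversion, every nucleus summed to 10000. How nuclei were filtered, how human nuclei were chosen and which program did the scaling were not given in the sources used here. Only the table of human nuclei was analysed here, with 890 PP and 4000 PPMV nuclei and 33537 features. Gene symbols were used as the file gives them. Of the features, 22315 matched a symbol and 893 an older symbol in a list of RefSeq genes of GRCh38.p14, which was used for names alone.

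The plan made before the data were examined assumed UMI counts, and for log values it named a difference of mean log values with no fold. The file held log values from which whole UMI counts could be recovered, by dividing each inverted value by the smallest positive one of its nucleus, with 100% of the results whole within a tolerance of 1e-06. The planned methods for counts were therefore used, and the difference of mean log values was kept as an alternative. No further filter on nuclei was applied.

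Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scanpy 1.11.5 were used, with leidenalg 0.10.2 for clustering. The 2000 most variable genes of the log values gave 30 principal components, 15 nearest neighbours by exact search and Leiden clusters at resolution 1.0, for both libraries together and with no integration. This gave 19 clusters. The 25 marker lists were fixed before the data were examined, but the rule that turned markers into names was chosen after the clusters were seen and went through 5 versions. In its last version a marker counted when its mean CPM in the cluster was at least 2 times the lower quartile over clusters, with 10 CPM added to both, and at least 10% of nuclei held it. A name needed at least 3 such markers and 0.5 of its list, its own marker had to come first among the 50 leading genes, and no rival list could have more markers among the 10 leading genes. The step from the fourth to the fifth version took nuclei out of the alpha-like and cycling-like classes. The neighbour search was also changed from approximate to exact after a look at the clusters. Doublets were called with Scrublet in each library and were kept. It called 10 of 890 PP nuclei and 0 of 4000 PPMV nuclei, so the caller did not work for PPMV and leaving out its calls tests little.

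Shares of nuclei were given with exact Clopper-Pearson 95% intervals, and ratios of shares with a 95% interval from the delta method. Gene levels were the summed UMI of a class over the class total, as UMI per 1000000 UMI of the class (CPM). The level of a gene in 1 library has an exact Poisson 95% interval, and the log2 ratio of PPMV over PP has an exact conditional binomial 95% interval. All of these intervals cover counting error only. They do not include differences between grafts, animals, microvessel isolations or library preparations, and no test between the conditions was made. For gene levels they also leave out the spread between nuclei of a class. A gene with 0 UMI in 1 library was set to a floor of 3 counts, its ratio is a bound, and no ratio was given where both libraries were at or under the floor.

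The main gene comparisons were made for all nuclei and for the classes with at least 50 nuclei in each library, which were acinar-like, alpha-like and delta-like nuclei. Beta-like, enterochromaffin-like, ductal-like and cycling-like nuclei, with at least 20 nuclei in each library, were added after the data were seen. Mesenchymal-like nuclei were too few in PP (15 nuclei) for a comparison of genes. Where a summed list is given for them, it rests on these few nuclei, with 20 UMI in PP for immediate early genes. The genes named were chosen by a rule fixed before the data were examined. It took the 5 highest and the 5 lowest log2 ratios among genes with at least 50 UMI and an interval that excludes no difference, the 2 members of each gene list with the largest absolute log2 ratio, and 13 fixed genes. Named after their values were seen were CPA1, CTRB1, CEL, RBPJL, REG1A, CLPS, FOS and HSP90AA1 in acinar-like nuclei, ABCC8 and FN1 in delta-like nuclei, TPH1 in enterochromaffin-like nuclei, GHRL, INS and PPY in the cluster led by PPY, and COL3A1 and PRSS2 in mesenchymal-like nuclei. RBPJL in cycling-like nuclei was also named after its values were seen. For each of 31 gene lists fixed before the data were examined, the median log2 ratio over members with at least 20 UMI was set against 10000 random lists of the same size matched on mean expression. A list is described as outside the random range when its median lay beyond the central 95% of those lists. Members at least 1.5-fold higher or lower with an interval that excludes no difference were counted as a description of these libraries.

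To compare shares of nuclei with a hormone UMI across libraries of unequal depth, each nucleus was thinned to 3338 UMI, the 10th percentile over all nuclei. Shallower nuclei were left out.

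The ratio step was tested on simulated counts of the 16698 genes with at least 50 UMI, drawn from their means over both libraries. The true ratio lay in the interval for 95.9% of unchanged genes, and 4.12% of their intervals excluded no difference. The interval excluded no difference for 79.4% of genes changed 1.5-fold, 87.0% of those changed 2-fold and 100% of those changed 4-fold. Of 100 simulated unchanged lists, 3% lay outside the random range, against 100% of 20 raised lists. Genes were drawn as independent Poisson counts, the model that the intervals assume, so these rates check the arithmetic alone. The draws held no spread between nuclei and no genes that vary together. They had the depth of all nuclei, so they do not cover the smaller classes. Median UMI per nucleus was 5431 in PP and 7870 in PPMV.

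Alternatives chosen before the data were examined were, for shares, Leiden resolutions of 0.5 and 2.0, 15 principal components, no doublets, components with each library's mean removed (library regressed), naming by the highest marker score and a minimum of 500 detected genes. For genes and lists they were scaling by the median of ratios, scaling by the trimmed mean of M values, the mean of per-nucleus shares, no doublets, thinned nuclei, minimums of 200 UMI for genes and 100 UMI for list members, and the ratio of summed UMI. For hormones they were the 25th percentile of UMI, at least 3 UMI of each hormone and no doublets. Depth was also taken without nuclei over 5% mitochondrial UMI. Chosen after seeing the data were the approximate neighbour search, 3 other naming rules, library regressed together with naming without the rule on the first marker, the PPY-led cluster counted as endocrine, acinar-like nuclei without the clusters over 95% from PPMV, lists without nuclei over 1% mitochondrial UMI, and genes without the nucleus holding most of their UMI in each library. Mouse and rat nuclei were not analysed here.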

Results

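Nuclei from subcutaneous grafts of H1-derived pancreatic progenitors were profiled 14 weeks after transplantation. Progenitors had been embedded in collagen alone (PP) or together with rat microvessel fragments (PPMV). Each group is 1 library that merges 3 grafts. The human part of the PP library held 890 nuclei and 6111596 UMI, with a median of 5431 UMI and 2596 genes per nucleus. The human part of the PPMV library held 4000 nuclei and 38951755 UMI, with a median of 7870 UMI and 3275 genes per nucleus. With 1 library per group there is no replicate, so each difference describes these 2 libraries. All intervals are 95% intervals and cover counting error only.

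The first comparison asks which human cell classes the grafts held with and without microvessels. The largest class in both libraries was acinar-like, the class that carries digestive enzyme genes, at 49.8% of PP nuclei (46.4 to 53.1%) and 60.8% of PPMV nuclei (59.3 to 62.3%). The 4 named endocrine classes together made up 30.7% of PP nuclei (27.7 to 33.8%) and 11.9% of PPMV nuclei (10.9 to 12.9%), a log2 ratio of -1.37 (-1.56 to -1.18). Each of them was a smaller share of PPMV. Glucagon-producing alpha-like nuclei were 12.2% of PP and 4.43% of PPMV, somatostatin-producing delta-like nuclei 11.01% and 5.33%, insulin-producing beta-like nuclei 2.81% and 1.03%, and serotonin-type enterochromaffin-like nuclei 4.61% and 1.08%. Mesenchymal-like nuclei, the connective tissue class, were 1.69% of PP (15 nuclei) and 7.33% of PPMV (293 nuclei), a log2 ratio of 2.12 (1.38 to 2.86).

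Cycling-like nuclei were 4.16% of PP and 7.40% of PPMV, with a log2 ratio of 0.83 (0.35 to 1.31). They held RBPJL, an acinar transcription factor gene, at 1208 CPM in PP and 1241 CPM in PPMV. This lay within the span of the acinar-like clusters (964 to 2700 CPM), so the class is not clearly apart from acinar-like nuclei. Ductal-like nuclei were 4.16% and 5.50%, and the interval of their log2 ratio, -0.09 to 0.90, includes 0. Over 13 settings the cycling-like ratio lay between 0.28 and 1.02 and the ductal-like ratio between -0.17 and 1.29. Clusters without a name held 9.55% of PP and 7.13% of PPMV nuclei. The largest of them, led by COL25A1, was 6.07% of PP and 4.88% of PPMV, and 2 other naming rules counted it as cycling-like. Another, led by the hormone genes PPY and GHRL, was 3.48% and 2.08%. Counting this cluster as endocrine put the endocrine share at 34.2% of PP and 13.9% of PPMV. Within that endocrine total, alpha-like nuclei were 35.9% in PP and 31.8% in PPMV, delta-like nuclei 32.2% and 38.2%, and beta-like nuclei 8.22% and 7.36%, with overlapping intervals. Enterochromaffin-like nuclei were 13.5% (9.86 to 17.8%) and 7.72% (5.64 to 10.3%).

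Mesenchymal-like nuclei were 1 cluster led by COL3A1, of which 95.1% came from PPMV, and acinar-like nuclei were spread over 7 clusters, led in number by the GNAL cluster in PP (127 nuclei) and the TMEM266 cluster in PPMV (551 nuclei). PPMV nuclei were deeper, with a median of 7870 UMI against 5431 UMI. Several of the digestive enzyme genes that mark acinar-like nuclei were themselves higher in PPMV. With library regressed from the principal components, the acinar-like log2 ratio turned from 0.29 to -0.29, and a cluster of 5 PP and 687 PPMV nuclei with 13 of the 17 acinar markers was left unnamed. With that cluster named acinar-like the ratio was 0.18 (0.08 to 0.28). The same setting put 458 PP and 0 PPMV nuclei in 1 acinar-like cluster, so it parted the libraries in this class rather than joined them. The mesenchymal-like ratio lay between 0.56 and 2.15 over 13 settings, and the endocrine log2 ratio between -1.43 and -1.29 over 14 settings.

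**Figure D1:**
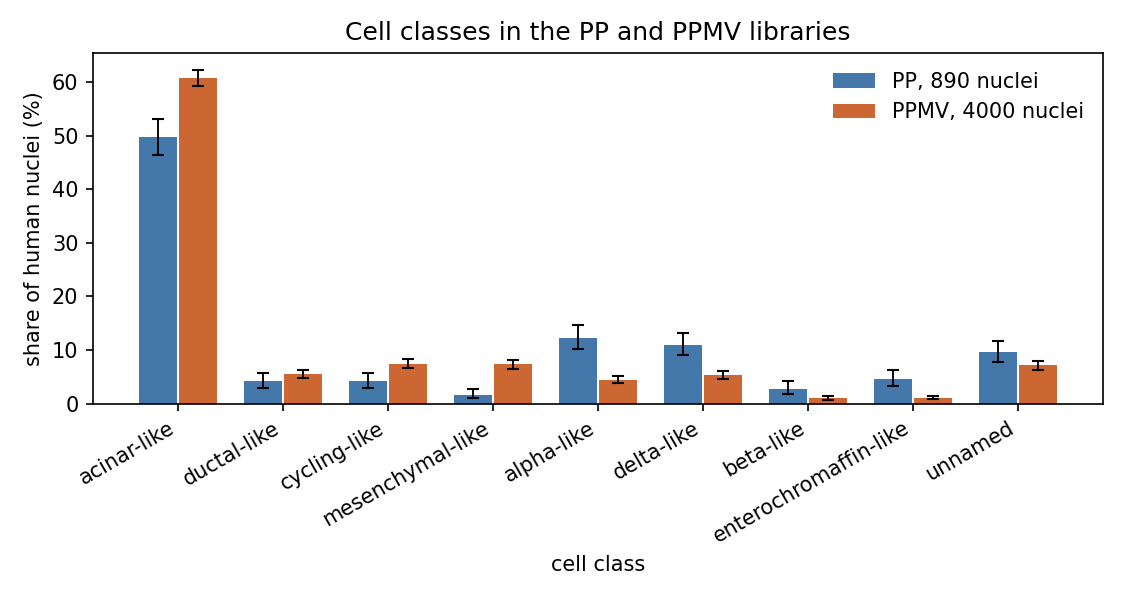
Share of human nuclei (%) in each cell class for the PP library (890 nuclei) and the PPMV library (4000 nuclei), with exact 95% binomial error bars that cover counting error only. Alpha-like nuclei stand at 12.2% in PP and 4.43% in PPMV, and mesenchymal-like nuclei at 1.69% and 7.33%.

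The next comparison asks how much hormone RNA the endocrine nuclei held. In the class named for it, each main islet hormone was near the same level in both libraries. INS, the insulin gene, stood at 12645 CPM in PP beta-like nuclei and 13509 CPM in PPMV (log2 ratio 0.10, 0.02 to 0.17). GCG, the glucagon gene, stood at 5813 and 6323 CPM in alpha-like nuclei (log2 ratio 0.12, 0.07 to 0.18). SST, the somatostatin gene, stood at 7205 and 9141 CPM in delta-like nuclei (log2 ratio 0.34, 0.29 to 0.40).

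The cluster led by PPY and GHRL differed in make-up. PPY, the pancreatic polypeptide gene, was at 3892 CPM in PP (3597 to 4205) and 1764 CPM in PPMV (1670 to 1862). GHRL, the ghrelin gene, was at 48.4 CPM (20.9 to 95.4) and 1092 CPM (1019 to 1170), and INS at 115 CPM (69.2 to 180) and 922 CPM (855 to 994). This cluster of 31 PP and 83 PPMV nuclei held 13 of the 17 alpha cell markers, and was left unnamed because PPY came first among its leading markers, under a rule added after the clusters were seen. Of 3 other naming rules, 2 named it alpha-like and 1 epsilon-like, after the class that makes ghrelin.

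In beta-like nuclei the amyloid peptide gene IAPP was at 1451 CPM in PP and 958 CPM in PPMV (log2 ratio -0.60, -0.83 to -0.37). The beta cell transcription factor gene PDX1 was at 109 and 15.1 CPM (log2 ratio -2.85, -4.35 to -1.53) on 18 and 7 UMI. MAFA, a transcription factor of mature beta cells, had 6 and 16 UMI (log2 ratio -0.08, -1.50 to 1.57), and UCN3, a maturity marker, had 0 UMI in PP and 4 in PPMV. SST in beta-like nuclei was higher in PPMV (log2 ratio 4.91), but 84.1% of its PPMV UMI came from 1 nucleus, and without the top nucleus of each library the ratio was 2.66.

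**Figure D2:**
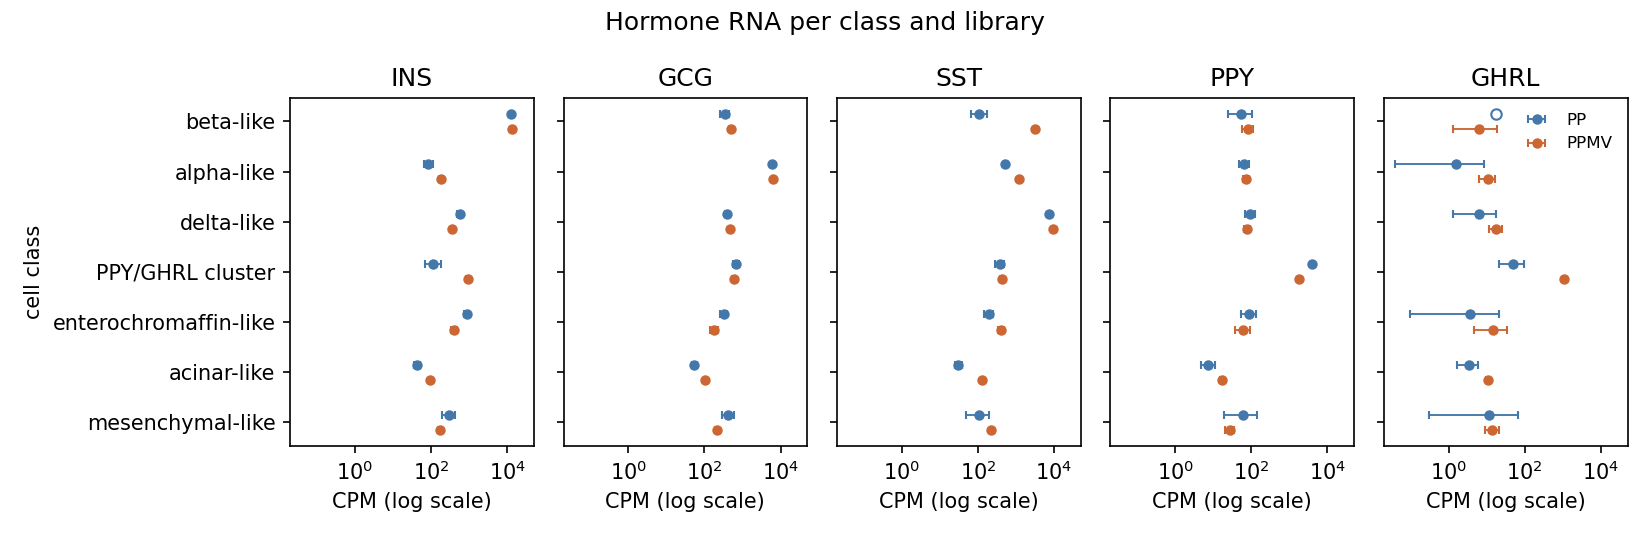
Level of 5 hormone genes in CPM on a log axis, per cell class, in PP and PPMV. Points carry exact 95% Poisson error bars, and the open circle marks 0 UMI drawn at the floor of 3 counts. INS in beta-like nuclei stands at 12645 CPM in PP and 13509 CPM in PPMV, and the high SST of PPMV beta-like nuclei is 84.1% from 1 nucleus.

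Thinning to 3338 UMI left out 246 of 890 PP and 243 of 4000 PPMV nuclei. Among named endocrine nuclei it left out 109 of 273 in PP and 74 of 474 in PPMV. The thinned shares therefore describe the deeper nuclei, more so in PP. After thinning, INS was seen in 92.9% of 14 PP and 100% of 39 PPMV beta-like nuclei. GCG was seen in 94.3% and 99.4% of alpha-like nuclei, and SST in 96.4% and 99.4% of delta-like nuclei. Without thinning the shares were 96.0% and 100%, 95.4% and 98.9%, and 97.96% and 100%. Acinar-like nuclei, which should lack these hormones, gave the background: INS in 10.7% of PP and 25.5% of PPMV nuclei, GCG in 14.4% and 28.8%, and SST in 9.58% and 32.7%. Their median depth was 6014 UMI in PP and 8144 UMI in PPMV. Without thinning the acinar-like shares were 22.3% and 49.1% for INS, 26.4% and 52.9% for GCG, and 15.3% and 57.6% for SST. This background was more frequent in PPMV than in PP acinar-like nuclei. In 3 smaller classes the intervals of PP and PPMV overlapped for each of these hormones after thinning. With 9 to 30 PP nuclei these intervals are wide and do not show an equal background. Ductal-like nuclei (30 PP and 208 PPMV) had INS in 26.7% and 23.6%, GCG in 20% and 22.1% and SST in 16.7% and 26.0%. Mesenchymal-like nuclei (9 PP and 203 PPMV) had INS in 44.4% and 39.4%, GCG in 44.4% and 40.4% and SST in 33.3% and 36.5%. Cycling-like nuclei (30 PP and 292 PPMV) had INS in 16.7% and 28.8%, GCG in 6.67% and 24.3% and SST in 10.0% and 28.4%. Without thinning the intervals parted in cycling-like nuclei for GCG (16.2% and 51.7%) and SST (13.5% and 61.1%). They also parted in ductal-like nuclei for GCG (27.0% and 52.7%) and SST (29.7% and 60.0%). Those of INS, and all of mesenchymal-like nuclei, overlapped. PPMV nuclei were deeper in these classes.

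Nuclei with a UMI of 2 or more hormones were 54.3% of PP (46.3 to 62.1%) and 72.8% of PPMV (68.1 to 77.1%) named endocrine nuclei after thinning, and 63.0% and 90.5% before. The classes did not share this gap evenly. After thinning, the alpha-like share was 37.1% in PP (25.9 to 49.5%) and 75% in PPMV (67.4 to 81.6%). Beta-like shares were 57.1% and 76.9%, and delta-like shares 75% and 76.9%. Enterochromaffin-like shares went the other way, at 54.2% and 34.4%. Outside alpha-like nuclei, the PP and PPMV intervals of each endocrine class overlapped. Acinar-like nuclei with 2 or more were 4.79% in PP and 25.8% in PPMV after thinning. Since background hormone UMI differed between the libraries, the gap in endocrine nuclei is not read as co-expression. With at least 3 UMI of each hormone, the thinned shares were 10.98% (6.64 to 16.8%) and 18.3% (14.6 to 22.4%). Acinar-like nuclei are no matched background for these shares, because an alpha-like, beta-like or delta-like nucleus has its own hormone and needs only 1 other. Enterochromaffin-like nuclei, also counted here as endocrine, are not named for any of the hormones counted.

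The third comparison sets gene levels in PPMV against PP within each class. In acinar-like nuclei (443 PP and 2432 PPMV), several digestive enzyme genes were higher in PPMV. The trypsinogen genes PRSS1 and PRSS2 were higher by log2 ratios of 1.68 (1.61 to 1.75) and 2.20 (2.12 to 2.27), from 494 to 1584 CPM and from 472 to 2165 CPM. The genes are near-identical copies. CPA1, a carboxypeptidase gene, was higher by 1.20, CTRB1, a chymotrypsinogen gene, by 0.65, and CEL, a lipase gene, by 0.34, while RBPJL, an acinar transcription factor gene, stood at 1892 and 1855 CPM (log2 ratio -0.03, -0.07 to 0.01). The list of acinar and ductal genes had a median log2 ratio of 0.65, and 7 of its 11 measured members were at least 1.5-fold higher in PPMV. In delta-like nuclei, which should lack it, PRSS1 was at 64.0 CPM in PP and 605 CPM in PPMV. How much of the rise in acinar-like nuclei came from such background was not tested.

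Immediate early genes, which respond within minutes to stimulation or stress, had a median log2 ratio of 1.51 in acinar-like nuclei, with 14 of 17 measured members at least 1.5-fold higher in PPMV. EGR1 was higher by 2.88 (2.38 to 3.43), FOS by 2.01 (1.59 to 2.46), and FOSB, with 0 UMI in PP and 262 in PPMV, by at least 3.596 against the floor of 3 counts. Heat shock chaperone genes had a median of 1.03, with 9 of 12 members at least 1.5-fold higher. HSPA1A was higher by 2.40 (1.68 to 3.21), DNAJB1 by 1.87 (1.08 to 2.80) and HSP90AA1 by 1.41 (1.25 to 1.58). Without the acinar-like clusters led by MIR3681HG and CUZD1, of which 95.6% and 96.3% of nuclei came from PPMV, the medians were 0.74 for immediate early and 0.39 for heat shock genes, with EGR1 at 2.09, HSPA1A at 1.62 and DNAJB1 at 1.03.

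Ribosomal protein genes had a median log2 ratio of 0.87 in acinar-like nuclei (14 of 18 members at least 1.5-fold higher), led by RPS12 at 1.38 and RPS2 at 1.31. Interstitial matrix genes had a median of 0.81 (9 of 18), led by COL3A1 at 3.85 (2.29 to 6.14) and SPARC at 1.78. COL3A1 was at 1895 CPM in PPMV mesenchymal-like nuclei against 13.2 CPM in PPMV acinar-like nuclei. Hormone genes had a median of 1.17 (6 of 8), and hormones are background in this class. Proliferation genes had a median of 0.79 (4 of 18 higher and 1 lower), with CENPF at 3.09 on 2 and 123 UMI. Of these 18 genes, 13 had under 10 UMI in PP, and without the MIR3681HG and CUZD1 clusters the median was 0.51, within the random range. Inflammation and NF-kB targets had a median of 0.55 (6 of 15) and a ratio of summed UMI of 0.15, where LCN2 and CXCL8 had 0 UMI in PP and 67 and 99 in PPMV.

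Mitochondrially encoded genes had a median log2 ratio of 0.28 in acinar-like nuclei, and the unfolded protein response 0.23 with HSPA5, an ER chaperone, at 0.96. Their ratio of summed UMI was 0.14 and -0.07, and without nuclei over 1% mitochondrial UMI the mitochondrial median was 0.77. Cholesterol and lipid synthesis genes lay below the random range at -0.24, with 1 of 16 members at least 1.5-fold lower.

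The other 20 lists lay within the random range in acinar-like nuclei. Transcription factors of beta and alpha cell identity had medians of 0.12 and 0.38, beta cell maturation genes 0.21, glucose sensing and secretion genes 0.06, granule and exocytosis genes 0.03 and genes of monogenic diabetes 0.13. HIF targets of hypoxia had 0.00, glycolysis 0.14, oxidative phosphorylation and the citrate cycle 0.20, and p53 and apoptosis genes 0.15. Angiogenic ligands had 0.21, basement membrane genes -0.02, integrins 0.02, TGF-beta and BMP genes 0.21, Notch 0.10, Wnt -0.06, and insulin and IGF signalling -0.01. Interferon and MHC genes had 0.21, synaptic and axonal genes 0.16, and nuclear long noncoding RNAs 0.18. As a ratio of summed UMI, synaptic and axonal genes stood at 0.72, TGF-beta and BMP genes at -0.16, Notch at -0.13, HIF targets at -0.09, integrins at -0.06 and transcription factors of beta cell identity at -0.01. With median-of-ratios scaling the small medians of HIF targets (-0.07), integrins (-0.04), granule and exocytosis (-0.04) and glucose sensing and secretion genes (-0.01) lay below 0. Without the MIR3681HG and CUZD1 clusters, angiogenic ligands (0.32), TGF-beta and BMP genes (0.28) and genes of monogenic diabetes (0.22) lay above the random range. Among the lowest genes were the neuronal receptor gene CNTNAP4 (-2.53, -2.91 to -2.15), LINC01924 (-2.39), LHX5 (-2.05) and AC104151.1 (-2.64). The axon guidance receptor gene DCC stood at -2.56, but 59.8% of its PP UMI came from 1 nucleus and the ratio without the top nuclei was -1.55. The highest genes beside COL3A1 (AL049840.1, AC092167.1, ABCA8 and AL450332.1) each had 1 UMI in PP.

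In alpha-like nuclei (109 PP and 177 PPMV), held mostly by the cluster led by DCC and GCG in both libraries, G6PC2, a glucose-6-phosphatase of islet cells, was lower in PPMV, at a log2 ratio of -1.04 (-1.58 to -0.50) and -0.45 with each nucleus thinned. Also lower were SREBF1, a regulator of lipid synthesis, at -1.11 (-1.62 to -0.60), and CAMK2B at -1.07 (-1.50 to -0.64). The lists of glucose sensing and secretion (-0.22), lipid synthesis (-0.12) and glycolysis (-0.20) lay within the random range. TPH1, the enzyme of serotonin synthesis, was the lowest gene at -3.53, and -2.80 without the top nucleus of each library, which held 49.4% of its PP UMI. The unfolded protein response had a median of 0.44, with 6 of 18 members at least 1.5-fold higher. HSPA5 had 9 UMI in PP and 89 in PPMV (log2 ratio between 1.01 and 3.18). HERPUD1 was higher by 1.46 (0.78 to 2.22). HSPA5 was also higher in PPMV acinar-like nuclei, and a part from background RNA of that class was not excluded.

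Acinar and ductal genes had a median log2 ratio of 2.45 in alpha-like nuclei, with PRSS2 at 3.50 and CPA1 at 2.98, and the highest genes were REG1B, REG1A, REG3G, CLPS and MTTP, between 3.98 and 6.95. REG1A and CLPS were also higher in PPMV acinar-like nuclei, by 2.35 and 1.77. Lists above the random range also included hormones (0.45), p53 and apoptosis (0.78), proliferation (1.40), angiogenic ligands (0.66), interstitial matrix (0.57), Notch (0.41), interferon and MHC (0.65) and ribosomal genes (0.35). All 10 measured proliferation genes had under 10 UMI in PP, as did 6 of 14 angiogenic and 6 of 13 matrix genes. Mitochondrially encoded genes had a median of -2.50, but without nuclei over 1% mitochondrial UMI (3 PP and 0 PPMV alpha-like nuclei) the median was 1.37. Notch genes had -0.03, angiogenic ligands 0.23 and hormones 0.28 as a ratio of summed UMI. With a minimum of 100 UMI, p53 and apoptosis genes had 0.16, and without nuclei over 1% mitochondrial UMI interstitial matrix genes had 2.70. Of the lowest genes, SGCZ (-2.73) had 91.0% of its PP UMI in 1 nucleus and stood at -0.11 without the top nuclei.

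In delta-like nuclei (98 PP and 213 PPMV), genes of glucose sensing and secretion had a median log2 ratio of -0.32, below the random range, but only 2 of 16 members were at least 1.5-fold lower in PPMV and 0 higher. ABCC8, a subunit of the ATP-sensitive potassium channel, was at -0.63 (-0.84 to -0.42). Transcription factors of beta cell identity had a median of -0.35 (1 of 11 members at least 1.5-fold lower), with NKX2-2 at -0.93 (-1.60 to -0.24) and MLXIPL at -0.54 (-0.97 to -0.10). Without nuclei over 1% mitochondrial UMI this median was -0.22, within the random range. Synaptic and axonal genes had -0.24 (2 of 16 lower and 2 higher), with CSMD1 at -2.27 (-3.04 to -1.52). Genes of monogenic diabetes had -0.35 (5 of 16 lower and 2 higher), with CEL at 1.49, and 0.24 as a ratio of summed UMI.

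Interstitial matrix genes had the highest median of the lists in delta-like nuclei, at 2.13 (8 of 13 members at least 1.5-fold higher), but 10 of the 13 members had under 10 UMI in PP. COL3A1 had 1 UMI in PP and 84 in PPMV (log2 ratio 4.61, 2.10 to 9.93), and FN1 was at 2.60 (1.74 to 3.62). PPMV delta-like nuclei held 50.5 CPM of COL3A1, against 1895 CPM in PPMV mesenchymal-like nuclei. Acinar and ductal genes had a median of 1.91 with PRSS2 at 3.57, and REG1B was the highest gene at 5.68 on 3 and 528 UMI. Other lists above the random range were immediate early (0.99), inflammation and NF-kB (0.88), angiogenic ligands (0.82), interferon and MHC (0.77), Notch (0.65), proliferation (0.59), and insulin and IGF signalling (0.32). Under 10 UMI in PP were 7 of 8 immediate early, 5 of 8 inflammation and 6 of 10 Notch genes. Notch genes had -0.09 with a minimum of 100 UMI. The sensor of the unfolded protein response ERN1 was higher by 1.47 (0.83 to 2.17). Mitochondrially encoded genes had -1.55, and -0.27 without nuclei over 1% mitochondrial UMI. INS in delta-like nuclei (-0.62) had 59.9% of its PP UMI in 1 nucleus and stood at 0.46 without the top nuclei, and MYOCD (-2.10) stood at 0.58.

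**Figure D3:**
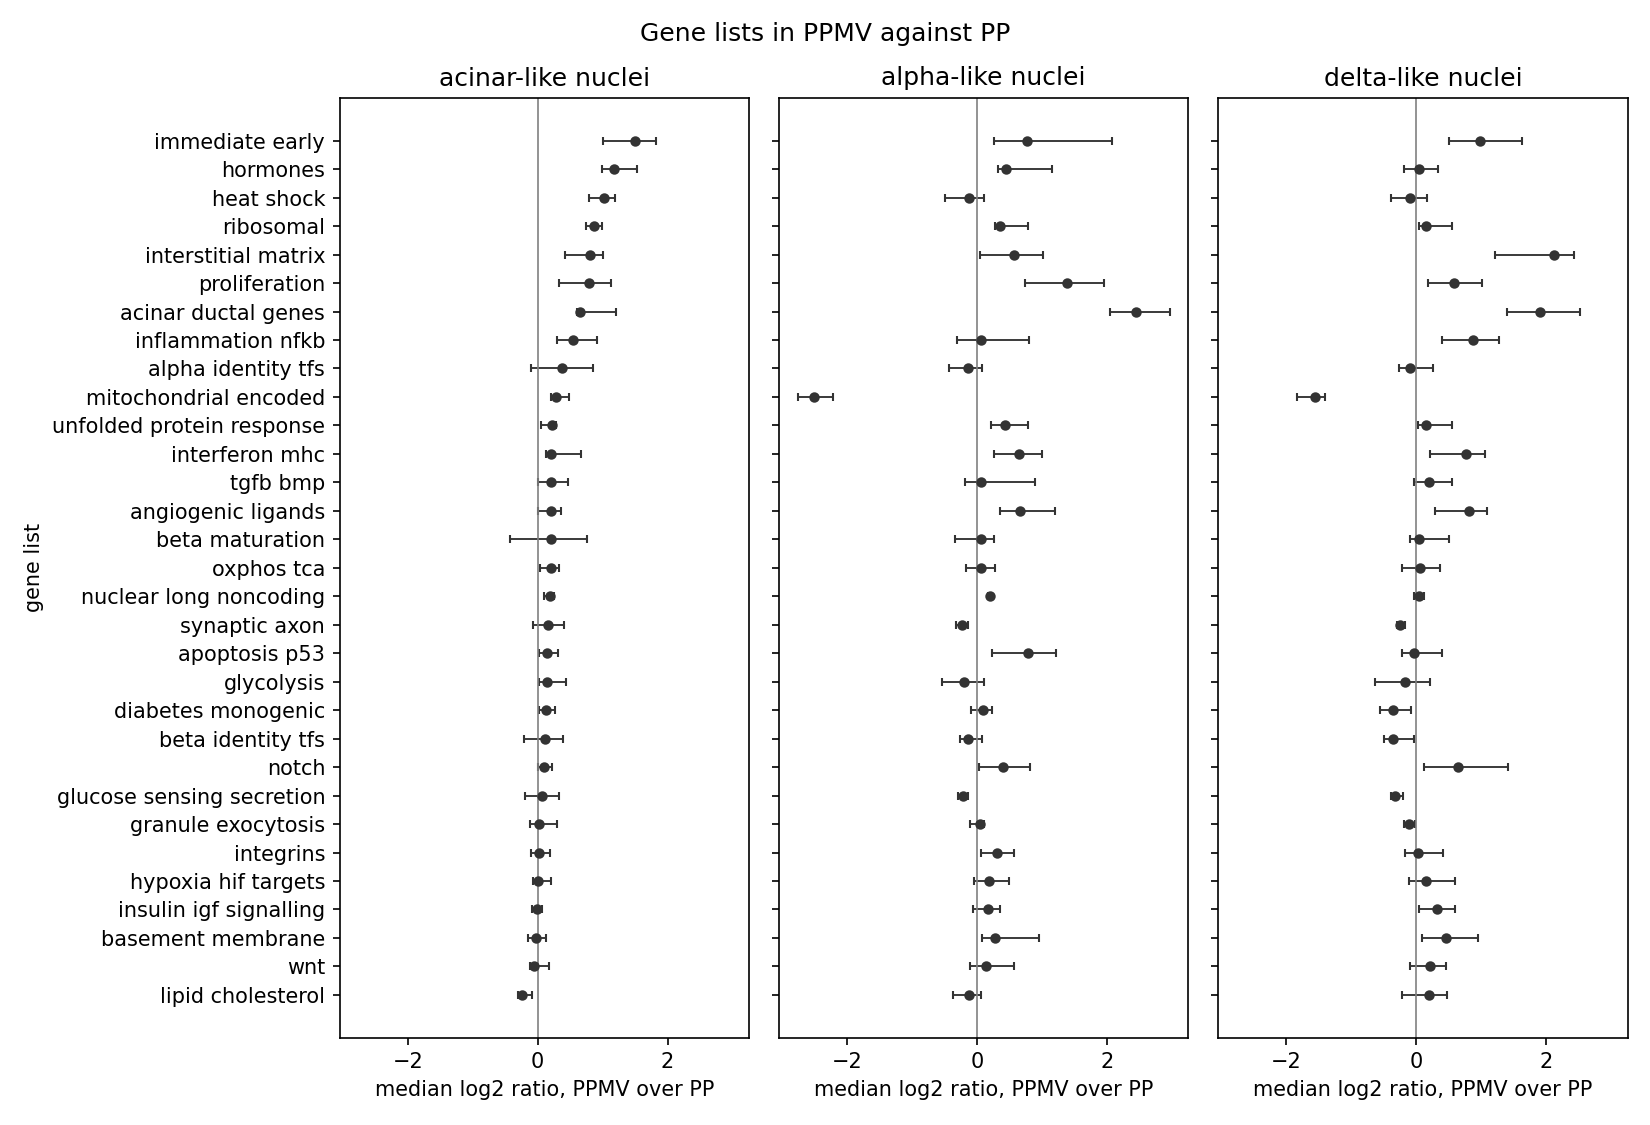
Median log2 ratio of PPMV over PP for each gene list in acinar-like, alpha-like and delta-like nuclei, with error bars from Poisson resampling of the UMI (95%, counting error only). Immediate early genes stand at 1.51, 0.77 and 0.99, and heat shock genes at 1.03, -0.12 and -0.09 (0.11 in delta-like nuclei with a minimum of 100 UMI), while the low mitochondrial medians of alpha-like and delta-like nuclei rest on a few PP nuclei.

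Genes of other classes were a measured background in both libraries. In mesenchymal-like nuclei INS was at 295 CPM in PP and 172 CPM in PPMV, and GCG at 425 and 209 CPM. SST went the other way, at 106 and 224 CPM. The PP values rest on 15 nuclei. PRSS2 had 2 UMI in PP mesenchymal-like nuclei, under the floor of 3 counts, and stood at 776 CPM (737 to 817) in PPMV mesenchymal-like nuclei, a class that should lack it.

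VEGFA, the main growth factor for blood vessels, was lower in PPMV in each of the 7 named classes compared. In acinar-like nuclei it stood at 135 CPM in PP and 79.3 CPM in PPMV (log2 ratio -0.77, -0.92 to -0.62), in alpha-like nuclei at 274 and 184 CPM (-0.57, -0.84 to -0.29), and in delta-like nuclei at 149 and 99.3 CPM (-0.58, -0.99 to -0.16). Over the 7 classes the log2 ratio lay between -1.12 in beta-like and -0.57 in alpha-like nuclei, and every interval lay below 0. The classes come from the same 2 libraries and share their background RNA, so they are not 7 independent findings. How far background RNA low in VEGFA lowered the values of PPMV endocrine classes was not tested. The list of HIF targets to which VEGFA belongs had medians of 0.00, 0.18 and 0.15 in acinar-like, alpha-like and delta-like nuclei, all within the random range, and -0.09 and -0.0044 as a ratio of summed UMI in acinar-like and alpha-like nuclei. ANGPT2, a vessel-destabilising ligand, was higher in PPMV acinar-like nuclei by 1.41 (0.78 to 2.12).

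**Figure D4:**
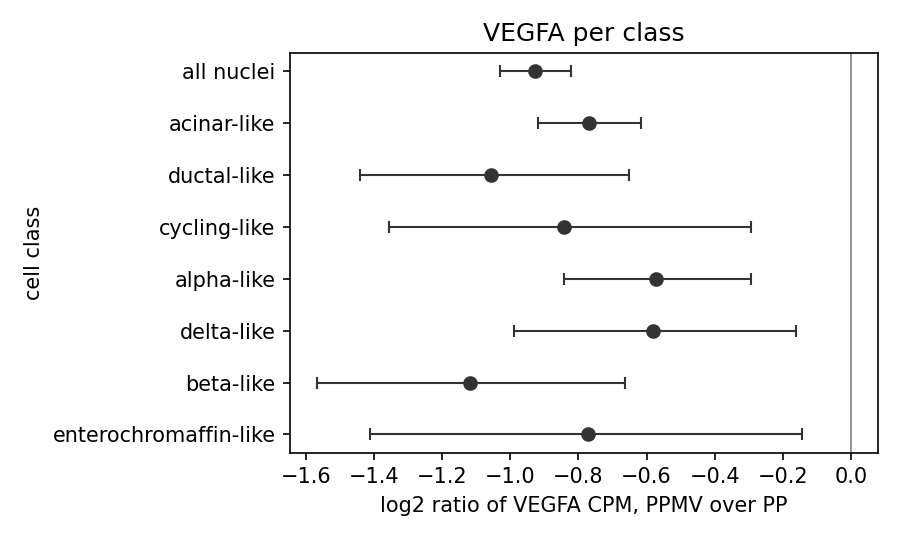
Log2 ratio of VEGFA CPM in PPMV over PP for all nuclei and for 7 cell classes, with exact conditional binomial 95% error bars (counting error only). Every point lies below 0, between -1.12 in beta-like and -0.57 in alpha-like nuclei. The points come from the same 2 libraries and are not independent.

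Over all nuclei together, the ratios follow the shares of the classes as well as levels within them. Several endocrine lists were lower in PPMV: beta cell maturation had a median log2 ratio of -1.28 (10 of 14 members at least 1.5-fold lower), granule and exocytosis genes -0.97 (17 of 24), and glucose sensing and secretion genes -0.95 (12 of 22). As a ratio of summed UMI, beta cell maturation stood at -0.77 and granule and exocytosis genes at -0.58. Transcription factors of alpha cell identity had a median of -1.18 but 0.15 as a ratio of summed UMI. Without nuclei over 1% mitochondrial UMI, 7 of the 14 beta cell maturation genes were at least 1.5-fold lower. CHGA, a granule protein gene of endocrine cells, was at -1.49 (-1.57 to -1.40). Immediate early genes stood at 1.62 (14 of 19 higher), acinar and ductal genes at 1.01 (9 of 12) and interstitial matrix genes at 0.87 (15 of 22). The highest gene was FOSB at 5.07 (3.20 to 8.12). The lowest 5 genes, TMPRSS11B, KRT13, RHCG, LINC02487 and KRT4, include keratins of layered epithelia, and in PP their UMI came largely from a few nuclei: 73.5% of TMPRSS11B and 37.4% of KRT13 from 1 nucleus each.

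Among the classes with fewer nuclei, enterochromaffin-like nuclei (41 PP and 43 PPMV) held less CHGA in PPMV, at 1392 CPM against 3004 CPM (log2 ratio -1.11, -1.28 to -0.95). TPH1 in this class stood at 1130 CPM in PP (1006 to 1264) and 392 CPM in PPMV (329 to 464). Ductal-like nuclei (37 PP and 220 PPMV) had a median of 1.27 for MHC and interferon genes, above the random range, with 7 of 14 members at least 1.5-fold higher and 10 of 14 under 10 UMI in PP. Among them were B2M at 2.66 (1.85 to 3.62) and HLA-B at 3.30 (1.73 to 5.58). Cycling-like nuclei (37 PP and 296 PPMV) had medians of 1.57 for immediate early (8 of 15 members at least 1.5-fold higher) and 1.42 for heat shock genes (9 of 12), and -0.47 for proliferation genes (5 of 18 lower). All 15 immediate early and 6 of the 12 heat shock genes had under 10 UMI in PP. Each of these PP classes had under 50 nuclei, so single nuclei weigh heavily.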

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

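No paired analysis was possible because each library merges 3 grafts, so results were compared by direction and size alone. Chosen after seeing the data were the approximate neighbour search, the other naming rules, library regressed together with a looser naming rule, the counting of the PPY cluster as endocrine, the sets without clusters mostly from PPMV or without nuclei rich in mitochondrial UMI, and the sets without a gene's top nucleus. Unless the construction of an alternative shows it, the cause was not tested. A value is said to reverse only where the main interval excluded 0.

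The lower shares of endocrine-like nuclei in PPMV kept their direction in every setting that gave a value. The log2 ratio lay between -1.43 and -1.29 for all named endocrine classes, between -1.53 and -1.27 for alpha-like, between -1.84 and -1.14 for beta-like and between -1.29 and -1.003 for delta-like nuclei. The enterochromaffin-like ratio went from -2.10 to -1.29 with naming by the highest marker score, and the class had no value at Leiden resolution 0.5 or 2.0 or with the approximate search. Beta-like nuclei had none with 15 components.

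Other classes moved more. The acinar-like log2 ratio of 0.29 was -0.29 with library regressed, where a cluster of 5 PP and 687 PPMV nuclei was left unnamed, and 0.18 with library regressed and that cluster named. Regressing library put 458 PP and 0 PPMV nuclei in 1 acinar-like cluster, so it parted the libraries in this class. It was 0.15 without doublets, 1.20 by the highest marker score, 0.46 with the approximate search and 0.52 with markers at least 4 times the lower quartile. The mesenchymal-like ratio of 2.12 was 1.38 at Leiden resolution 0.5, 1.15 at 2.0, 1.09 with library regressed under both naming rules and 0.56 by the highest marker score. The ductal-like ratio of 0.40 was 1.29 with 15 components and -0.17 by the highest marker score. The cycling-like ratio of 0.83 was 0.28 both without the rule on the first listed marker and with naming by the best list alone. The filter at 500 genes left out 0 nuclei and tests nothing, and the filter at 5% mitochondrial UMI left out 3.

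Hormone shares depend on depth. Thinned to the 25th percentile, GCG was seen in 100% of PPMV alpha-like and SST in 100% of PP delta-like nuclei, and in acinar-like nuclei INS was seen in 16.0% of PP and 33.1% of PPMV, GCG in 33.9% of PPMV and SST in 40.0% of PPMV. Asking for 3 UMI of each hormone took the share with 2 or more from 54.3% to 10.98% of PP and from 72.8% to 18.3% of PPMV endocrine nuclei, and from 4.79% to 0.563% and from 25.8% to 0.541% of acinar-like nuclei. The acinar-like share is no matched background, since an alpha-like, beta-like or delta-like nucleus has its own hormone.

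Taken as a ratio of summed UMI, where abundant members weigh most, lists reversed as follows: in all nuclei alpha identity 0.15, monogenic diabetes 0.27, insulin and IGF -0.000326 and Notch -0.0781. In acinar-like nuclei TGF-beta and BMP went to -0.16 and the unfolded protein response to -0.0674, Notch to -0.0279 in alpha-like nuclei, and monogenic diabetes to 0.24 in delta-like nuclei. Where the main interval included 0, values that left it with a change of sign were -0.0901 for hypoxia and -0.13 for Notch in acinar-like nuclei and -0.14 for granule genes in alpha-like nuclei. Values that moved without turning were, in all nuclei, beta identity -0.47, beta maturation -0.77, granule genes -0.58, hypoxia 0.00081, unfolded protein response 0.14, TGF-beta and BMP 0.0322, Wnt 0.0831, inflammation 0.37 and synaptic genes -0.59. In acinar-like nuclei they were mitochondrial 0.14, Wnt -0.14, insulin and IGF -0.10, inflammation 0.15 and synaptic genes 0.72. In alpha-like nuclei they were hormones 0.28, angiogenic ligands 0.23, synaptic genes -0.11 and monogenic diabetes 0.50, and in delta-like nuclei Notch 0.0338.

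With a minimum of 100 UMI, which leaves fewer members, Notch reversed to -0.0745 in alpha-like and -0.0942 in delta-like nuclei, and basement membrane genes to -0.0198 in delta-like nuclei. Alpha identity moved to -0.70 and glucose sensing to -1.13 in all nuclei. Inflammation in alpha-like nuclei turned from 0.0646 to -0.45 and lipid genes in delta-like nuclei from 0.20 to -0.35, with main intervals that included 0. In alpha-like nuclei heat shock moved to -0.59 and apoptosis to 0.16, and in delta-like nuclei acinar and ductal genes moved to 2.56. With median-of-ratios scaling, acinar and ductal genes moved to 0.58, lipid genes to -0.31 and Wnt to -0.12 in acinar-like nuclei, and nuclear long noncoding RNAs to 0.0250 in all nuclei.

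Without nuclei over 1% mitochondrial UMI, mitochondrial genes reversed to 0.62 in all nuclei and 1.37 in alpha-like nuclei, and moved to 0.77 in acinar-like and -0.27 in delta-like nuclei. The low values thus rested on a few nuclei. Interstitial matrix genes moved to 1.18 in all and 2.70 in alpha-like nuclei, acinar and ductal genes to 1.31, immediate early genes to 1.74 and lipid genes to -0.12 in all nuclei. Without the acinar-like clusters over 95% from PPMV, heat shock genes moved to 0.39 and immediate early genes to 0.74.

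For 313 gene ratios, 2140 alternatives gave a value: 142 moved out of the interval, 13 reversed and 1985 did neither. Of the moved ones 4 changed sign from a main interval that included 0. Over all alternatives another 24 list values, between -0.14 and 0.14, and 20 gene values, between -0.25 and 0.54, changed sign and count as unmoved, because the main interval included 0 and, on the same scale, held the new value. The rescalings shift all genes of a class alike, by at most 0.0683, and test little. The difference of mean log values is on another scale, so it was compared by direction alone. Taken as the difference of mean log values, SST and INS in all nuclei turned to 0.20 and 0.12, and INS and MYOCD in delta-like nuclei to 0.19 and 0.00750. With each nucleus thinned, CACNA1C in acinar-like nuclei turned to -0.0573, IGFBP2 and NKX2-2 in alpha-like nuclei to -0.16 and 0.26, and INS and SYT7 in delta-like nuclei to 0.00370 and 0.23. In delta-like nuclei INS was 0.22 by mean shares and 0.46 without the top nuclei, and MYOCD was 1.34 without doublets and 0.58 without the top nuclei. Of the 10 highest and lowest genes, those with at least 200 UMI were 2 for all nuclei, 4 for acinar-like, 4 for alpha-like and 2 for delta-like nuclei.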

Other observations

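Tests chosen only after their results were seen were the endocrine share without mesenchymal-like and cycling-like nuclei, and the immediate early genes without the cluster led by CUZD1. Each pattern was found and tested on the same 2 libraries, so what follows are hypotheses. Group and library cannot be separated in this design.

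The cluster led by PPY and GHRL held these 2 hormones in different proportions in the 2 libraries. Whether single nuclei held both was not analysed here. In PP it was mostly PPY, at 3892 CPM against 48.4 CPM of GHRL, and in PPMV both hormones were abundant, at 1764 and 1092 CPM. At Leiden resolution 0.5 a separate cluster led by GHRL appeared, with 2 PP and 21 PPMV nuclei. Whether its nuclei came from the cluster led by PPY was not traced.

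Endocrine-like nuclei were a smaller share of PPMV than of PP. A difference in depth was argued against as the whole cause, since the log2 ratio standardised over quintiles of UMI was -1.15 (-1.34 to -0.95). Without mesenchymal-like and cycling-like nuclei in the denominator the ratio was -1.23 (-1.41 to -1.04). This value follows from the shares of these classes, which were too small to account for the gap. It is arithmetic on the same counts and adds no separate evidence. Acinar-like nuclei, the largest class, stayed in the denominator. The values leave open that grafts with microvessels kept or formed more acinar-like tissue per endocrine cell, and also unequal nucleus recovery or chance between grafts, which 1 library per group may not resolve. A smaller share is not a smaller number, and endocrine cells per graft were not analysed here.

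Mesenchymal-like nuclei were a larger share of PPMV than of PP. To look for rodent nuclei counted as human, the share of UMI on clone-named and LINC genes, poorly conserved between species, was compared. In PPMV mesenchymal-like nuclei it was 0.960 times (0.952 to 0.968) that in PPMV acinar-like nuclei. This argues against nuclei whose UMI were mostly cross-mapped rodent reads. It cannot decide on rodent nuclei holding mostly background human RNA, whose share would be near that of the whole library. That share was 3.57% over all PPMV and 3.38% in PPMV mesenchymal-like nuclei, which held 528 CPM of PRSS1. Depth was argued against by a standardised log2 ratio of 2.66 (1.94 to 3.39). A wider human connective tissue compartment around microvessels is 1 hypothesis that could be tested by staining, and a difference between 3 merged grafts stays open. The size of the ratio depends on how the class is drawn, down to 0.56 by the highest marker score.

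Immediate early genes were higher in PPMV acinar-like nuclei. The summed UMI of the list were also higher in alpha-like nuclei by 0.81 (0.35 to 1.30), in beta-like by 0.82 (0.11 to 1.59), in delta-like by 1.23 (0.79 to 1.69) and in cycling-like by 1.94 (1.497 to 2.416), while the intervals included 0 in ductal-like (0.26, -0.02 to 0.54), mesenchymal-like (0.52, -0.12 to 1.24) and enterochromaffin-like nuclei (0.64, -0.09 to 1.41). The mesenchymal-like ratio rests on 20 UMI of 15 PP nuclei, and the beta-like ratio also rests on 20 UMI in PP. In PPMV the list stood at 403 CPM in acinar-like, 127 CPM in alpha-like, 213 CPM in beta-like and 232 CPM in delta-like nuclei. Endocrine nuclei of PPMV also held background RNA of acinar-like nuclei, such as 605 CPM of PRSS1 in delta-like nuclei. How much of the rise in endocrine classes came from this background was not tested. In alpha-like nuclei 4 of the 5 measured members had under 10 UMI in PP and the list median lay within the random range. Heat shock genes were higher by 1.04 in acinar-like nuclei, or 0.50 without the CUZD1 cluster, and at -0.32 (-0.51 to -0.13) in alpha-like nuclei. Heat shock genes were also higher in cycling-like (1.14, 0.94 to 1.35) and ductal-like nuclei (0.64, 0.41 to 0.87). Cycling-like nuclei held RBPJL at the level of acinar-like clusters, so for both lists they add little beside the acinar-like result. The heat shock intervals included 0 in beta-like, delta-like, enterochromaffin-like and mesenchymal-like nuclei. A response to retrieval or nucleus preparation cannot be told apart from an effect of microvessels, because library and group coincide and the alpha-like interval spans the bound set for the test. The cluster led by CUZD1 was argued against as the whole cause, since the ratio without it was 0.78 (0.65 to 0.91), and no biological explanation was tested.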
